A study of Mus musculus with 6 samples.

How the data were processed

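RNA was measured in 6 libraries of bone marrow LSK cells from mice, all labelled Phf6fl-R274X/Y. The Y marks males, which have a single copy of the X-linked gene Phf6. Of the libraries, 3 carried the floxed R274X allele without Cre (floxed controls) and 3 carried the same allele with Vav1-Cre (R274X libraries). LSK stands for lineage-negative, Sca-1-positive, c-Kit-positive cells, the bone marrow gate in which blood stem cells and multipotent progenitors are enriched. Per the labels' protocols, total RNA was extracted with TRIzol and turned into libraries with an Illumina TruSeq RNA kit. Whether strand was kept is not given in the sources used here. The labels gave the genotype of each library and no replicate numbers, so replicates were numbered within a group and were not paired. No batch or date was given.

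The authors deposited, per the file headers, a whole-number read count and an FPKM value for each of 54532 Ensembl genes in each library. Bowtie and the mouse genome build mm8 are named in the submitters' processing notes, without a version of Bowtie. The counting tool and the annotation are not given in the sources used here. Of the gene identifiers, 54409 matched GENCODE release M21 of the assembly GRCm38, and 123 did not. The gene lengths implied by the deposited counts and FPKM values equalled the merged exon lengths of that release, within 0.01%, for 94.4% to 94.6% of genes with over 200 counts. The identifiers and lengths therefore belong to a later annotation than mm8, and coordinates given here are those of GRCm38. The library sizes implied by the deposited FPKM values equalled median-ratio size factors times the geometric mean of the totals in all 6 libraries, so the authors' FPKM values are already scaled between libraries and do not use the raw totals. Gene symbols came from a table of Ensembl identifiers. Where several identifiers shared a symbol, it stayed with that of the highest total count. Unmatched identifiers held 0.031% to 0.048% of the counts.

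Total counts per library were 18106065, 17200917 and 17697834 in the controls and 16896472, 16070348 and 15406314 in the R274X libraries. No pair of libraries agreed within sampling noise, since the chi-square per gene between replicates was at least 12.05. Intervals and floors cover counting error only, because the reads carry no molecular identifiers.

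The deposited counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default count filter (minimum count 10), the robust option and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05, and a second count used in addition a change of at least 2-fold. CPM values were scaled with the TMM factors. Gene lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01, over 34 lists with at least 5 tested members. Shares of counts and the Phf6 level were compared with exact two-sided permutation tests in SciPy 1.17.1, for which the smallest possible p with 3 against 3 libraries is 0.1. The groups, the design, the 34 lists (940 entries), the rule for named genes and most alternative settings were set before the data were examined.

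The lists covered stem cell identity, HOX genes, quiescence, proliferation, lymphoid, myeloid and megakaryocyte-erythroid priming, rRNA synthesis, ribosomal proteins, NuRD, SWI/SNF and Polycomb, interferon, TNF and NF-kB, JAK-STAT, p53, Notch and Wnt, TGF-beta and BMP, immediate early genes, heat shock, the unfolded protein response with ATF4 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, antigen presentation, adhesion and apoptosis. Further lists held markers of neutrophils, macrophages and monocytes, B cells, T and NK cells, erythroid cells, mast cells with basophils and eosinophils, endothelial and stromal cells, and plasma and dendritic cells. Named genes were Phf6, 14 fixed genes, the 12 largest increases and 12 largest decreases, and up to 4 members with the smallest p from each list described. The largest changes were taken among genes past the threshold with no overlap between the groups and a group mean of at least 5 CPM. Predicted and RIKEN symbols were passed over, which removed 0 increases and 2 decreases. Genes outside this rule are said to have been chosen after their values were seen.

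The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no count filter, a mean count of at least 50, the robust option off, leaving out each library, and limma on log2 of the deposited FPKM plus 1 (genes with a mean of at least 0.5) with other pseudocounts, filters, scalings and options. For the lists, camera with an estimated correlation and fry were also run. Offsets per library for gene length and GC content, removal of all immunoglobulin genes and the immunoglobulin percent as a covariate were added after the data were seen.

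The scripts were tested on simulated counts for this comparison with 200 changed genes among 14385 tested. edgeR called 46.3% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 93.9% of those changed 4-fold, and 10.4% of its calls were false. DESeq2 called 78.5% of all changed genes, with 16.5% of its calls false. camera called the list that had been raised and 0 of 33 others. Genes were simulated independently of each other, so this does not measure false calls among lists whose members move together. The estimated correlation within the real lists ran from -0.03, for JAK-STAT targets among others, to 0.88, for B cell markers. The length and GC offsets moved a planted slope from -0.098 to -0.002 per doubling of length. On the real counts the same offsets moved the slope only from -0.158 to -0.089, while the median log2 fold change went from 0.20 to 0.03 in the shortest 10% of genes and from -0.13 to 0 in the longest 10%. Genes of families with near-identical copies, among them immunoglobulin V segments, hemoglobin, stefin and Ly6 genes, are uncertain, because the counting could divide reads between copies.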

Results

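The libraries came from LSK cells, the stem and progenitor gate of mouse bone marrow. The male mice had a floxed allele of the X-linked gene Phf6, meant to give R274X, a premature stop codon, where Cre is active. Phf6 encodes a PHD finger protein of the nucleus and nucleolus. In 3 control libraries the allele was present without Cre, and in 3 R274X libraries it was combined with Vav1-Cre, which is active in blood cells. The study addressed how the mutation relates to stem cell self-renewal and repopulation. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Cre is present in all R274X libraries and in no control, so its own effect is part of the comparison.

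Phf6 RNA was 3.51-fold lower in the R274X libraries. The gene (ENSMUSG00000025626, protein-coding, chromosome X, 52912266 to 52956943, GRCm38) measured 31.6 ± 1.98 CPM in controls and 9.01 ± 1.08 CPM in R274X libraries (SD, n = 3 each). The control values were 31.77, 29.59 and 33.53 CPM, and the R274X values were 8.47, 10.25 and 8.29 CPM, from 600, 552 and 623 against 131, 155 and 124 counts. The log2 fold change was -1.81 (SE 0.123, edgeR adjusted p = 6.67e-06), and the exact permutation p of the 6 values was 0.1, the smallest possible. The deposited FPKM values were 4.52 ± 0.309 and 1.29 ± 0.155.

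**Figure D1:**
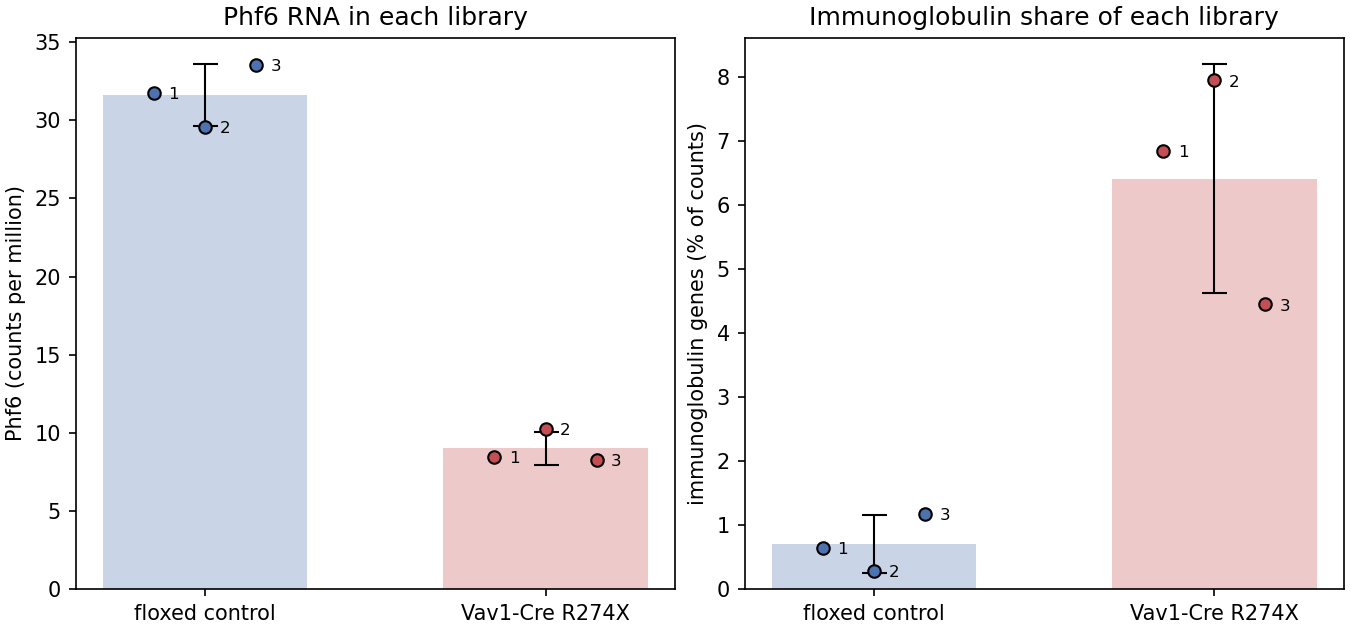
Phf6 in CPM, scaled counts (left) and immunoglobulin genes as a percent of all counts (right) in 3 control and 3 R274X libraries; points are libraries with their replicate number, bars are means and error bars are SD. Phf6 lies between 29.59 and 33.53 CPM in controls and between 8.29 and 10.25 CPM in R274X libraries, while the immunoglobulin share lies at or below 1.18% in controls and at or above 4.45% in R274X libraries.

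Immunoglobulin transcripts took a larger share of the R274X libraries. They made up 0.65%, 0.29% and 1.18% of counts in the controls and 6.85%, 7.95% and 4.45% in the R274X libraries, a ratio of means of 9.08 (exact two-sided permutation p = 0.1, the smallest possible). With this many counts the 95% binomial intervals (Wilson score) were no wider than 0.02 percentage points, so counting error was far below the spread between libraries. The share of 7 abundant neutrophil genes was 2.55 ± 0.685% and 2.37 ± 1.19% (SD, n = 3 each, exact permutation p = 0.9). This difference in immunoglobulin share accompanies every gene group described here.

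Among 14608 tested genes, 2621 differed between the groups, 1469 higher and 1152 lower in the R274X libraries. At least 2-fold changes were found in 603 genes, 454 higher and 149 lower, and 48 of those 454 were immunoglobulin genes. Values of the groups did not overlap for 5432 genes (37.2%, where chance gives 10%). The division between directions depended on scaling: 56% of calls were higher with TMM, 45.9% (1215 higher, 1430 lower) with upper-quartile scaling and 36.7% (663 higher, 1144 lower) with quantile normalization of the deposited FPKM. Fewer genes passed without control 1 (1462), control 2 (1242), R274X 1 (1218) or R274X 2 (1340), and the 2-fold counts were 343, 324 and 354 without control 2, R274X 1 and R274X 2.

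**Figure D2:**
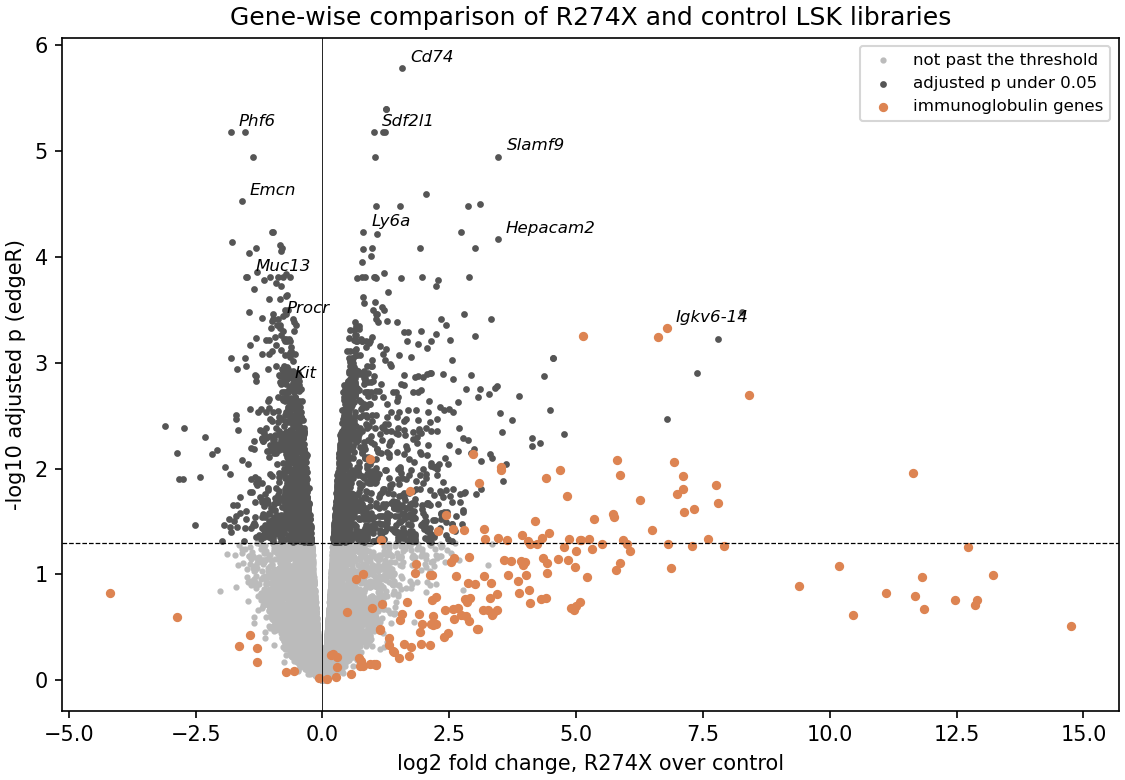
Log2 fold change of each tested gene (R274X over control, horizontal) against -log10 of its edgeR adjusted p (vertical); the dashed line marks an adjusted p of 0.05 and orange points are immunoglobulin genes. Phf6 is among the strongest decreases, and fitted changes of genes with 0 counts in all controls, at the far right, depend on the prior count.

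The largest decreases after Phf6 were in Camsap3, a microtubule minus-end binding protein (5.84 ± 0.187 to 1.67 ± 0.465 CPM), Sema6b, a semaphorin, and Bdh2, a dehydrogenase. Emcn, the sialomucin endomucin of endothelium and stem cells, fell 3.02-fold (19.8 ± 0.96 to 6.54 ± 0.558 CPM, adjusted p = 2.96e-05). Muc13, a transmembrane mucin, fell 2.79-fold from 120.1 ± 15.9 to 43.0 ± 6.12 CPM (SD, n = 3 each, adjusted p = 0.000156). The others of the 12 were Vdr (the vitamin D receptor), Sdsl, Col4a2 (a basement membrane collagen), Sema3d, Myof (myoferlin) and Npdc1. The log2 fold changes of these 6 genes ran from -1.53 for Vdr to -1.44 for Npdc1, and all 12 stayed past the threshold whichever library was left out.

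All of the 12 largest increases were immunoglobulin V segments, which encode the variable part of antibody chains and form families of similar genes whose read assignment is uncertain. Igkv8-18 had 0 counts in all controls and was at least 438-fold higher in the R274X libraries, against a floor of 3 counts over the group. Igkv1-88 rose from 18.7 ± 11.6 to 2590 ± 1160 CPM (adjusted p = 0.0157) and Ighv6-3 from 8.02 ± 6.16 to 1120 ± 734 CPM (SD, n = 3 each, adjusted p = 0.026). The remaining segments were Ighv1-59, Igkv12-98, Ighv2-9, Igkv6-32, Ighv12-3, Ighv5-16, Ighv1-61, Igkv6-14 and Ighv1-50, with log2 fold changes from 6.61 to 7.79. Of the 12, 9 lost the threshold when a library was left out: 8 without control 1, 7 without control 2, 6 without control 3, 6 without R274X 1, 7 without R274X 2 and 1 without R274X 3, with adjusted p of up to 0.216.

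Outside immunoglobulin genes, the 12 largest increases, a set chosen after the values were seen, began with Wnt10a (a Wnt ligand, log2 fold change 3.74), Chst1 (a sulfotransferase, 3.62), Slamf9 (3.47) and Hepacam2 (3.45). Slamf9 rose 11.1-fold, from 1.25 ± 0.42 to 13.9 ± 2.96 CPM (SD, n = 3 each, adjusted p = 1.13e-05). Derl3, which acts in degradation of misfolded proteins of the endoplasmic reticulum, rose 8.17-fold and Epcam, an adhesion molecule, 7.40-fold. Cacna1h, Sit1, Eaf2, Il10 (the cytokine interleukin-10), Fxyd6 and Cldn7 completed the set. Chst1 lost the threshold without control 1 (adjusted p = 0.0586), Sit1 without control 2 (0.0527), and Derl3 without control 1 (0.07) or R274X 1 (0.0715).

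Stem cell identity genes were mostly lower in the R274X libraries. Of 35 tested members 22 fell, 2 rose and 11 did not pass, against 23 and 2 adjusted over the list alone, and the median log2 fold change was -0.61. Tie1, an endothelial and stem cell receptor, fell 2.47-fold (51.5 ± 9.51 to 20.8 ± 1.06 CPM), Ifitm1 1.98-fold and Etv6, a transcription factor needed in adult stem cells, 1.65-fold. Ly6a, which encodes the gate marker Sca-1, rose 1.74-fold from 141.7 ± 5.07 to 247 ± 15.6 CPM (SD, n = 3 each, adjusted p = 5.83e-05). HOX genes, transcription factors active in early progenitors, fell in 7 of 10 tested members with none rising (8 fell adjusted over the list alone; median -0.69), among them Hoxa10 (1.78-fold) and Hoxa5 (1.75-fold). When control 1, 2 or 3 or R274X 1, 2 or 3 was left out, in that order, 21, 18, 20, 19, 19 and 23 stem cell identity genes fell and 1, 1, 1, 1, 2 and 3 rose, and 4, 4, 4, 4, 4 and 5 HOX genes fell. camera gave adjusted p = 1.14e-10 for stem cell identity and 0.000154 for HOX genes. With an estimated correlation its adjusted p was 0.222 for both, and directional fry gave an adjusted p of 0.00495 for both.

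Most fixed stem and progenitor markers that passed were lower. Kit, the stem cell factor receptor of the gate, had a log2 fold change of -0.71 (adjusted p = 0.00159), Procr, the receptor EPCR, -0.87 (0.000391), Mecom -0.76 (0.00189), Hlf -0.52 (0.00907), Cd34 -0.62 (0.000715) and Flt3 -0.34 (0.00877). Hlf lost the threshold without control 2 (-0.48, adjusted p = 0.0558). Slamf1 (-0.61, adjusted p = 0.228), Cdkn1c (-0.67, 0.171), Mpo (-0.93, 0.205) and Mki67 (0.21, 0.0716) did not pass. Cd48 (0.09, adjusted p = 0.461) did not pass either and had the opposite sign (-0.23, adjusted p = 0.0438) under quantile normalization of FPKM. Ubtf, a factor of rRNA gene transcription, stood at 0.08 (0.511).

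Many cell cycle genes rose by small amounts. Of 44 tested members 26 rose, none fell and 18 did not pass (33 rose adjusted over the list alone), with a median of 0.30. Ccna2, encoding cyclin A2, rose 1.56-fold (144.6 ± 9.53 to 225.7 ± 22.7 CPM), Rrm2, a subunit of ribonucleotide reductase, 1.72-fold and E2f2 1.84-fold. camera gave adjusted p = 3.5e-13, and adjusted p = 0.361 with an estimated correlation. Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, rose in 25 of 46 members with none falling (31 adjusted over the list alone; median 0.30), including Cox7b (1.49-fold), Atp5k (1.79-fold) and Cox6a1. The camera adjusted p was 5.9e-13, and adjusted p = 0.469 with an estimated correlation. With control 1 to 3 and then R274X 1 to 3 left out in turn, 15, 15, 21, 16, 15 and 30 cell cycle genes and 15, 8, 17, 11, 17 and 30 oxidative phosphorylation genes rose. Transcripts of the mitochondrial genome took a smaller share of counts in the R274X libraries, 1.677 ± 0.055% against 2.003 ± 0.215% (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Short genes were higher in the R274X libraries in general, by a median of 0.20 in the shortest 10% of genes against -0.13 in the longest 10%.

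Some genes of the unfolded protein response and of antigen presentation were higher, fewer than those that did not pass. The list of the unfolded protein response and ATF4 targets had 13 members that rose, 1 that fell and 14 that did not pass among 28 (18 and 1 adjusted over the list alone; median 0.29). Sdf2l1, an endoplasmic reticulum chaperone component, rose 2.01-fold (65.1 ± 2.96 to 130.8 ± 2.78 CPM, adjusted p = 6.67e-06), Xbp1 2.44-fold and Pdia4, a protein disulfide isomerase, 1.71-fold. In the antigen presentation list 8 of 17 members rose, none fell and 9 did not pass (8 adjusted over the list alone; median 0.25). Its smallest p-values belonged to class II genes: Cd74, the invariant chain, rose 2.95-fold (300.7 ± 28.6 to 886.8 ± 19.2 CPM, adjusted p = 1.66e-06), H2-Ab1 2.38-fold, H2-Eb1 2.34-fold and H2-Aa 2.28-fold. Leaving out control 1 to 3 and then R274X 1 to 3 gave 8, 9, 9, 8, 8 and 15 rises in the first list and 6, 6, 7, 7, 7 and 7 in the other. camera gave adjusted p = 1.72e-07 and 1.78e-05 for these lists, against adjusted p = 0.327 and 0.361 with an estimated correlation. Markers of B cells, of plasma and dendritic cells and of macrophages were higher in the same libraries. Whether the rises in these 2 lists came from such cells or from LSK cells was not tested.

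**Figure D3:**
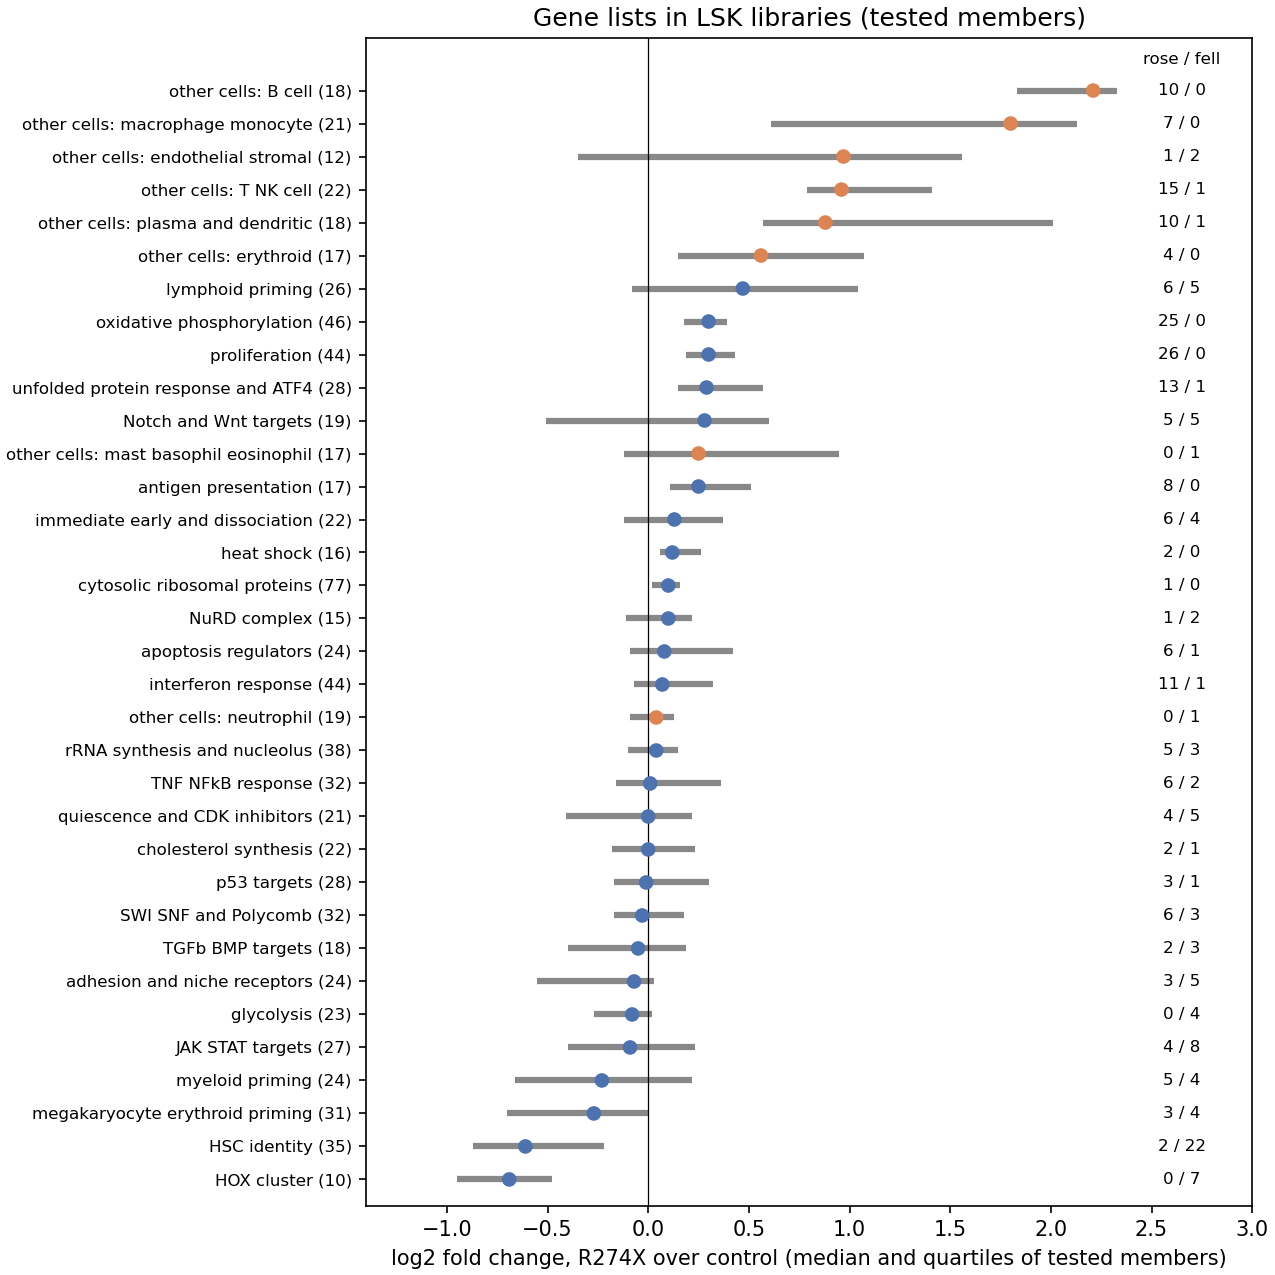
Median (points) and quartiles (bars) of the log2 fold change, R274X over control, of the tested members of 34 gene lists, with the number of tested members in brackets and the numbers that rose and fell at an adjusted p under 0.05 at the right; orange points are markers of other cell types. Medians run from -0.69 for HOX genes to 2.21 for B cell markers, and the ribosomal protein median of 0.10 becomes -0.26 under quantile normalization of FPKM.

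Markers of several mature cell types that the gate should exclude were higher in the R274X libraries. Of 18 tested B cell markers 10 rose and none fell (17 adjusted over the list alone), with a median of 2.21. Blk, a kinase of B cell receptor signalling, rose 3.44-fold (6.40 ± 1.57 to 22.1 ± 6.71 CPM) and Fcrla 4.79-fold, while Cd22 (log2 fold change 1.75) lost the threshold without control 2 or R274X 1 (adjusted p = 0.053 and 0.0535). T and NK cell markers rose in 15 of 22 members, and Lat fell (17 and 1 adjusted over the list alone; median 0.96). Cd3g, a chain of the T cell receptor complex, rose 4.43-fold from 1.33 ± 0.287 to 5.94 ± 1.5 CPM. Plasma and dendritic cell markers rose in 10 of 18 members, and Flt3 fell (14 and 1 adjusted over the list alone; median 0.88), with Cd209a 4.33-fold and Bst2 1.51-fold higher. Leaving out control 1 to 3 and then R274X 1 to 3 left 4, 2, 8, 2, 3 and 12 rises among B cell markers, 8, 8, 15, 9, 11 and 11 among T and NK cell markers and 5, 6, 8, 5, 5 and 10 among plasma and dendritic cell markers. The camera adjusted p was 3.9e-13, 6.73e-07 and 7.29e-09 for these lists, against adjusted p = 0.365, 0.361 and 0.361 with an estimated correlation.

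Macrophage and monocyte markers rose in 7 of 21 members with none falling (14 rose and 1 fell adjusted over the list alone; median 1.80). The 4 smallest p-values belonged to Cd68, Slc40a1 (the iron exporter ferroportin), Adgre1 (F4/80) and Hmox1 (heme oxygenase), with log2 fold changes of 1.40, 1.80, 2.02 and 2.21. Each of them lost the threshold without control 1 (adjusted p from 0.0542 to 0.142) or without R274X 2 (0.0742 to 0.132). Erythroid markers rose in 4 of 17 members (6 adjusted over the list alone; median 0.56), led by Alas2, the heme synthesis enzyme of red cell precursors (2.73-fold). In the order control 1 to 3 and R274X 1 to 3 of the library left out, 1, 4, 3, 1, 1 and 6 macrophage markers and 4, 1, 3, 2, 5 and 2 erythroid markers rose. The camera adjusted p was 1.31e-08 and 0.000154, against adjusted p = 0.361 and 0.55 with an estimated correlation. Neutrophil markers were not called as a group: 1 of 19 fell, Stfa1 (1 adjusted over the list alone), and the median was 0.04 while the mean was -0.13 (camera adjusted p = 0.657). Without R274X 3 they were called as lower (median -0.4, camera adjusted p = 0.00262). The number that fell was 2 without control 1, R274X 2 or R274X 3. In mast cell, basophil and eosinophil markers 1 of 17 fell, Siglecf (1 adjusted over the list alone; median 0.25, adjusted p = 0.206), which lost the threshold without any of control 1, control 2, R274X 1 and R274X 2 (adjusted p from 0.0507 to 0.103). In endothelial and stromal markers 1 of 12 rose, Cdh5, and 2 fell, Emcn and Pdgfrb (3 and 2 adjusted over the list alone; median 0.97, adjusted p = 0.404). Cdh5 lost the threshold without control 1 (adjusted p = 0.0871), control 2 (0.158), control 3 (0.079), R274X 1 (0.174) or R274X 2 (0.171). Endothelial and stromal rises numbered 0, 1, 4, 0, 0 and 3 without control 1 to 3 and then R274X 1 to 3.

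**Figure D4:**
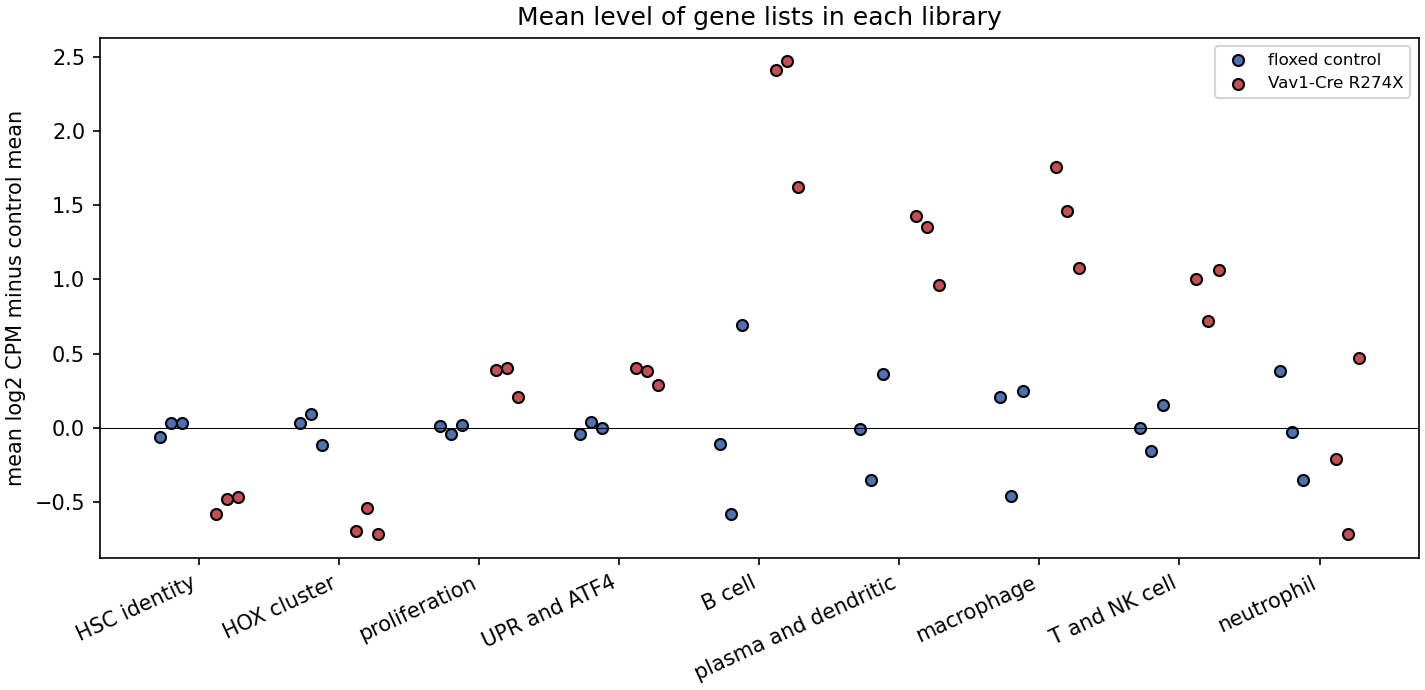
Mean log2 CPM of 9 gene lists in each library, minus the mean of the controls (vertical); each point is 1 library, blue for controls and red for R274X. B cell markers lie between 1.62 and 2.47 in R274X libraries and stem cell identity between -0.58 and -0.47, while neutrophil markers run from -0.72 to 0.47 in R274X libraries and from -0.35 to 0.38 in controls.

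Lineage priming lists were mixed. Lymphoid priming genes rose in 6 and fell in 5 of 26 members (9 and 5 adjusted over the list alone; median 0.47). Ighm is among the 6 (9.11-fold), and 9 members are also in another list, so this list partly repeats the B-lineage rise. The B-lineage genes Vpreb1 (5.11-fold, adjusted p = 0.0539) and Igll1 (4.66-fold, 0.058) did not pass, while Flt3, Notch1 and Satb1 fell. With immunoglobulin genes removed, 5 rose and 5 fell of 25 (median 0.34, camera adjusted p = 0.0196). Ccr9, a homing receptor of lymphoid and dendritic precursors, rose 1.95-fold and Cd52 1.94-fold, while Cd27 fell 1.39-fold. Its camera adjusted p was 0.0143 (adjusted p = 0.764 with an estimated correlation), and 0.0858 without control 2. Megakaryocyte-erythroid genes fell in 4 and rose in 3 of 31 members (7 and 3 adjusted over the list alone; median -0.27), with Tal1, a transcription factor of these lineages, 1.89-fold lower. The camera adjusted p of 0.0459 (adjusted p = 0.764 with an estimated correlation) passed 0.05 without control 1 (0.0573), control 2 (0.36), R274X 1 (0.0861) or R274X 2 (0.149). Myeloid priming genes rose in 5 and fell in 4 of 24 members (5 and 4 adjusted over the list alone; median -0.23, adjusted p = 0.243, and 0.00514 without R274X 3). Ly6c2 rose 2.32-fold and Sirpa 1.75-fold, while Cebpa, a myeloid transcription factor, fell 1.46-fold. Without control 1 to 3 and then R274X 1 to 3, lymphoid genes gave 5, 4, 6, 4, 5 and 8 rises and 3, 5, 3, 3, 4 and 5 falls, myeloid genes 4, 4, 3, 4, 3 and 4 and 3, 3, 4, 2, 3 and 6, and megakaryocyte-erythroid genes 3, 3, 3, 3, 3 and 3 and 3, 3, 4, 3, 3 and 9.

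Interferon response genes rose in 11 and fell in 1 of 44 members (12 and 1 adjusted over the list alone; median 0.07), with Bst2, Zbp1 and Ifit3 1.51-, 1.73- and 1.98-fold higher. The camera adjusted p was 0.0375 (adjusted p = 0.764 with an estimated correlation), and it was 0.0907 without control 1, 0.162 without control 3, 0.499 without R274X 3 and 0.0647 with offsets for gene length and GC content. Ribosomal protein genes had a median of 0.10 that turned to -0.26 under quantile normalization of FPKM, and 1 of 77 members rose (0 adjusted over the list alone), Rps27, which lost the threshold without control 2, control 3, R274X 1 or R274X 2 (adjusted p from 0.139 to 0.178). Their camera adjusted p was 0.00161 (adjusted p = 0.764 with an estimated correlation), and it was 0.23 without control 2, 0.263 without R274X 1 and 0.317 with offsets for gene length and GC content. Interferon genes that rose numbered 4, 6, 6, 4, 7 and 9 and ribosomal protein genes that rose 10, 0, 1, 0, 0 and 6 without control 1 to 3 and then R274X 1 to 3. In that order 1, 1, 1, 1, 0 and 4 interferon genes and 0, 0, 0, 1, 0 and 0 ribosomal protein genes fell. Of the 15 lists that camera called, none held with an estimated correlation. The smallest adjusted p there was 0.222, and 3 lists had an unadjusted p under 0.05. The estimated correlation was -0.02 for HOX genes and 0.07 for stem cell identity, against the preset 0.01. For HOX genes the lost call is therefore not due to members that move together. Whether this version of camera can call a changed list with 3 against 3 libraries was not tested. Other divisions of the 6 libraries gave up to 19 called lists. Each of those divisions mixed the genotypes on both sides and kept part of their difference, so they do not measure calls by chance.

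Chromatin and nucleolar lists, which touch the known partners of Phf6, were not called. The NuRD chromatin remodelling complex had 1 member that rose, Mbd2, and 2 that fell, Chd3 and Chd4, among 15 (2 and 3 adjusted over the list alone; median 0.10, adjusted p = 0.561). Chd4, the remodelling ATPase of that complex, had a log2 fold change of -0.26 (adjusted p = 0.0217), which missed the threshold without control 1, control 3, R274X 1 or R274X 2 (adjusted p from 0.0538 to 0.0702). Mbd2 and Chd3 also missed it, without control 1 (0.0526) and without R274X 1 (0.0537). In rRNA synthesis and nucleolar genes 5 rose and 3 fell of 38 (5 and 3 adjusted over the list alone; median 0.04, adjusted p = 0.509), and in SWI/SNF and Polycomb genes 6 rose and 3 fell of 32 (7 and 4 adjusted over the list alone; median -0.03, adjusted p = 0.758), with Arid1a 1.37-fold lower. Without control 1 to 3 and then R274X 1 to 3, rRNA and nucleolar genes gave 0, 0, 4, 1, 2 and 5 rises and 1, 0, 2, 1, 1 and 4 falls, and SWI/SNF and Polycomb genes 1, 1, 4, 1, 1 and 7 rises and 2, 2, 2, 2, 2 and 4 falls. In the same order, NuRD genes gave 0, 1, 1, 1, 1 and 5 rises and 1, 2, 1, 0, 1 and 2 falls.

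The other lists were not called by camera either; counts marked list alone are those adjusted over the list alone. Among quiescence genes 4 rose and 5 fell of 21 (7 and 6 adjusted over the list alone; median 0, adjusted p = 0.738), with Nr4a1 1.64-fold lower and Cdkn2c, a cell cycle inhibitor, 1.44-fold higher. Among JAK-STAT targets 4 rose and 8 fell of 27 (4 and 10 adjusted over the list alone; median -0.09, mean 0.01, adjusted p = 0.282), with Myc 1.67-fold lower and Ccnd3 1.97-fold higher. Notch and Wnt targets gave 5 rises and 5 falls of 19 (list alone 6 and 5; median 0.28, adjusted p = 0.642), TNF and NF-kB genes 6 and 2 of 32 (list alone 8 and 4; median 0.01, adjusted p = 0.642), immediate early genes 6 and 4 of 22 (list alone 7 and 4; median 0.13, adjusted p = 0.366), p53 targets 3 and 1 of 28 (list alone 3 and 1; median -0.01, mean 0.09, adjusted p = 0.79) and apoptosis regulators 6 and 1 of 24 (list alone 6 and 1; median 0.08, adjusted p = 0.1). TGF-beta and BMP targets gave 2 rises and 3 falls of 18 (list alone 4 and 4; median -0.05, adjusted p = 0.642), and cholesterol synthesis genes 2 and 1 of 22 (list alone 1 and 1; median 0, adjusted p = 0.989). Adhesion and niche receptors gave 3 rises and 5 falls of 24, with Robo4 and Esam 2.06- and 2.01-fold lower (list alone 4 and 6; median -0.07, also with Cdh2 at its bound, mean 0.17, adjusted p = 0.213). Glycolysis genes fell in 4 of 23 members, Ldhb most clearly at 1.78-fold (list alone 4; median -0.08, adjusted p = 0.0782, which became 0.00985 without control 3 and 0.00296 without R274X 3). Among heat shock genes 2 of 16 rose (list alone 2; median 0.12, adjusted p = 0.15, and 0.0242 without control 3), and mast cell, basophil and eosinophil markers were called without control 1 (5 rises, adjusted p = 0.0123) and neutrophil markers, lower, without R274X 3 (0.00262).

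The counts of these lists moved with the library left out, given here in the order control 1 to 3 and then R274X 1 to 3. Quiescence genes gave 2, 2, 4, 3, 2 and 4 rises and 6, 4, 5, 4, 4 and 5 falls. JAK-STAT targets gave rises of 2, 2, 2, 2, 3 and 3 and falls of 6, 5, 8, 6, 5 and 9, and Notch and Wnt targets of 2, 2, 3, 1, 1 and 5 and 3, 3, 5, 3, 3 and 4. TNF and NF-kB genes rose in 4, 3, 4, 3, 3 and 8 members and fell in 1, 1, 3, 1, 1 and 3, and immediate early genes rose in 5, 5, 6, 6, 4 and 7 members and fell in 4, 4, 4, 4, 4 and 4. p53 targets rose in 1, 3, 3, 2, 2 and 3 members and fell in 2, 2, 1, 1, 1 and 1, and apoptosis regulators rose in 3, 3, 5, 5, 3 and 6 members and fell in 0, 1, 0, 0, 0 and 1. TGF-beta and BMP targets rose in 1, 2, 2, 1, 3 and 5 members and fell in 1, 2, 2, 1, 2 and 4, and cholesterol synthesis genes rose in 0, 0, 2, 0, 0 and 3 members and fell in 0, 2, 0, 0, 0 and 1. Adhesion and niche receptors rose in 2, 2, 2, 2, 2 and 3 members and fell in 5, 4, 4, 4, 5 and 7. Glycolysis genes fell in 3, 3, 3, 1, 3 and 7 members, and heat shock genes rose in 2, 1, 1, 1, 2 and 4.

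Principal components of log2 CPM separated the genotypes along the first component, which held 64.3% of the variance. Controls lay at -39.0, -57.3 and -30.4 and R274X libraries at 50.7, 51.6 and 24.5. Pearson correlations across genes, which are not independent replicates, were 0.978 to 0.986 within groups and 0.929 to 0.963 between them.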

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

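The length and GC offsets, the removal of immunoglobulin genes and the immunoglobulin covariate were chosen after the data were seen; every other setting was planned. Phf6 stayed lower and past the threshold under every setting, with a log2 fold change of -1.91 to -1.76 when a library was left out and -2.31 (adjusted p = 0.0118) with the immunoglobulin covariate. Every gene called both in the main test and under another setting kept its direction. Of 206 named genes and lists, the other count settings gave 1356 values on the same side of the threshold, 19 that lost it and 26 that gained it, and leaving out a library gave 1061, 158 and 17. Leaving out a library moved the changed genes (2621) to between 1218 and 3295, the 2-fold genes (603) to between 324 and 828 and the called lists (15) to between 12 and 17; the cause was not tested. A mean count of at least 50 left 374 genes at 2-fold, with 11690 genes tested.

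On the deposited FPKM, limma called 1581 genes with a pseudocount of 1, 1532 with 0.1, 1570 with 0.5, 660 with no filter, 1504 with a mean of at least 2, 1585 with median centring and 1422 without the robust and trend options; the cause was not tested. The 2-fold genes numbered 302 with a pseudocount of 1, 375 with 0.5, 186 with no filter, 256 with a mean of at least 2, 288 with quantile normalization, 295 with median centring and 315 without those options. Quantile normalization turned the ribosomal list (-0.26), Cd48 (-0.23), Rps27 (-0.06), Rpl36 (-0.30) and Hspe1 (-0.04), of which the ribosomal list (adjusted p = 1.7e-10), Cd48 (0.0438) and Rpl36 (0.0292) passed there; the cause was not tested. camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05), fry called 12 in a direction and 31 mixed. Directional fry gave adjusted p = 0.00495 for stem cell identity, HOX, antigen presentation and JAK-STAT genes and 0.00498 for the unfolded protein response. It gave 0.0212 for cell cycle, macrophage, T and NK cell, plasma and dendritic cell and apoptosis genes. B cell markers had 0.0326 and oxidative phosphorylation genes 0.0396. Of lists camera called, it missed lymphoid (0.193), megakaryocyte-erythroid (0.424), ribosomal (0.424), interferon (0.377) and erythroid (0.0931) genes. camera has no DESeq2 counterpart, so lists were not run there.

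With the immunoglobulin percent as a covariate 75 genes passed, of which 72 changed at least 2-fold; 16 of the 75 were also called without it. This covariate nearly follows the genotype, so both compete for the same difference. Counting lists that passed with or without it and for which camera gave the other direction, it turned the lymphoid (-0.10), myeloid (0.94), megakaryocyte-erythroid (0.59), ribosomal (-0.08), NuRD (-0.15), glycolysis (0.33) and neutrophil (1.99) lists, all but the lymphoid and ribosomal lists with an adjusted p under 0.05. The lists of cell cycle (median 0, adjusted p = 0.963), oxidative phosphorylation (0.08, 0.197), B cell (0.13, 0.145) and plasma and dendritic cell genes (0.27, 0.0964) lost their calls there. Lists that gained a camera call there in an unchanged direction were quiescence (median -0.32, adjusted p = 0.00787) and SWI/SNF and Polycomb (-0.15, 0.0272). The mast cell, basophil and eosinophil list (1.01, 2.8e-06) gained one too. By the same rule it turned Sit1 (-0.05), Tcf3 (-0.09), Nfe2 (0.14), Smarca4 (-0.19), Ezh2 (-0.24), Xpc (0.02), Trp53inp1 (-0.14), Ski (0.04), Hk1 (0.14), Aldoc (0.12), Pdgfrb (0.18) and Cdh5 (-1.09), and none of these genes passed the threshold there. With the length and GC offsets the ribosomal (median 0.05, adjusted p = 0.317) and interferon (0.09, 0.0647) lists lost their calls.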

Other observations

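The tests of B cell markers above 1, of all cell types rising alike and of a common dilution factor were chosen after the results they measure were seen, as were the settings with length offsets and with immunoglobulin genes removed or as a covariate. The genes named in the next 2 paragraphs were also chosen after their values were seen.

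The immunoglobulin transcripts were of the IgM type in every library, with Ighm at 95.7% to 97.2% of heavy chain constant region counts in both groups. Ighm itself rose from 2797 ± 1640 to 25470 ± 7050 CPM (SD, n = 3 each, edgeR adjusted p = 0.0373), but when a library was left out it passed only without control 3 (0.0397), with an adjusted p of 0.135 without control 1, 0.0649 without control 2, and 0.126, 0.114 and 0.0563 without R274X 1, 2 and 3. Heavy chain V segments with at least 10 counts numbered 56, 42 and 63 in the controls and 90, 87 and 82 in the R274X libraries. The most abundant kappa V segment held 43.7%, 37.2% and 35.3% of kappa V counts in the controls and 20.4%, 15.9% and 14.8% in the R274X libraries. The 10 most abundant heavy chain V segments held 69.9%, 73.0% and 76.1% in the controls and 80.2%, 75.5% and 80.8% in the R274X libraries, and the 10 most abundant kappa V segments 77.3%, 82.7% and 80.6% against 80.3%, 77.2% and 86.2%, so the shares do not all point to a broader repertoire. These numbers also depend on how many immunoglobulin counts a library holds.

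Of the genes of the imprinted Dlk1-Meg3 region of chromosome 12, which were not tested as a group, the noncoding RNA Meg3 had 37, 27 and 17 counts in the controls and 4, 5 and 0 in the R274X libraries (adjusted p = 0.0127), and the noncoding RNA Rian had 22, 29 and 16 against 2, 2 and 2 (adjusted p = 0.00393). Meg3 lost the threshold without control 1 (adjusted p = 0.0605) or R274X 1 (0.0509), and Rian kept it whichever of the 6 libraries was left out. Dlk1 (adjusted p = 0.198) did not pass. Cdh2, encoding N-cadherin, had 0 counts in all controls and 23, 19 and 14 in the R274X libraries, at least 23-fold higher against a floor of 3 counts over the group. Hspb1, a small heat shock protein, went from 5, 3 and 0 to 43, 38 and 19 counts (adjusted p = 0.00206). Vav1, whose promoter drives the Cre, stood at 161.9 ± 4.45 and 160 ± 1.66 CPM.

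Of 18 tested B cell markers 10 rose, none fell and 8 did not pass (median 2.21; 4, 2, 8, 2, 3 and 12 rose without control 1 to 3 and then R274X 1 to 3), and the list was not called with an estimated correlation (adjusted p = 0.365). A scaling artefact from the abundant immunoglobulin genes is argued against by its direction. Those genes took 6.42% of counts in the R274X libraries and 0.707% in the controls, which by itself would lower other genes in the R274X libraries. With them removed before scaling, the remaining B cell markers kept a median log2 fold change of 2.14 (SE over libraries 0.45), above the 1 set as a bound. For the same reason this outcome was nearly fixed in advance and adds little. More RNA of B-lineage cells in the R274X libraries stays open: 15 of the 16 markers outside immunoglobulin genes lay above 1, but this count restates the rise and does not test its source. Of the 18 tested markers, 16 were at 5 CPM or more in the controls already and 4 are in another list, and a lineage-depleted gate would remove most mature B cells. Of plasma cell genes chosen after their values were seen, Irf4 rose 5.86-fold, Prdm1 4.36-fold and Sdc1 2.14-fold (edgeR adjusted p = 0.0208, 0.0479 and 0.0459). Without control 1 all of them lost the threshold (0.0938, 0.0609 and 0.0865). Jchain (9.53-fold, 0.0813), Tnfrsf17 (10.1-fold, 0.0519) and Mzb1 (5.79-fold, 0.0629) did not pass. Counts per gene do not show which cells held the RNA. Whether RNA of B-lineage genes came from the sort, from a marrow changed by the genotype or from altered transcription within LSK cells was not tested and stays open.

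Of 35 tested stem cell identity genes 22 fell, 2 rose (Ly6a and Socs2) and 11 did not pass, and the list was not called with an estimated correlation (adjusted p = 0.222). Gene length or GC content is argued against as the whole cause, as the median stayed at -0.55 with offsets (SE 0.04, from -0.61 without them), although the offsets removed only part of the linear length trend (slope -0.158 to -0.089 per doubling). B cell and neutrophil medians 2.17 apart (SE 0.8) argue against a lower share of LSK RNA with every other cell type rising alike. Squared deviations of the members from their common mean averaged 18.94 times their squared errors, which argues against a common dilution factor. Both measures restate values seen before, and neither counts against dilution by cells that express some members. Dilution by B-lineage cells that also express some of these genes may contribute: with the immunoglobulin percent as a covariate the median was -0.41, but the SE over libraries went from 0.05 to 0.15, so this cannot be told apart from genotype. An effect of the mutation or of Cre, or a shift among cells within the gate, also stays open and was not tested.

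Oxidative phosphorylation genes, short with a median of 1918 bases against 3927 for all tested genes, rose in 25 of 46 members (15, 8, 17, 11, 17 and 30 without control 1 to 3 and then R274X 1 to 3) and cell cycle genes in 26 of 44 (15, 15, 21, 16, 15 and 30 in the same order), neither list called with an estimated correlation (adjusted p = 0.469 and 0.361). Cell cycle genes had a median length of 4267 bases, above that of all tested genes. A trend that favours short genes would not raise them, and this length argues against it as the cause. With length and GC offsets the cell cycle median was 0.33 (SE 0.07, from 0.30), above the bound of 0.2. For length that outcome was fixed in advance, and GC content was not tested apart from length. A slope of -0.089 per doubling, of -0.158, remained. The oxidative phosphorylation median went from 0.30 (SE 0.07) to 0.23 (SE 0.05), against a bound of 0.2, so a part played by length or GC content cannot be told apart from a change of these genes. With the immunoglobulin percent as a covariate the cell cycle median was 0 (camera adjusted p = 0.963) and the oxidative phosphorylation median 0.08 (0.197), so cycling B-lineage cells may contribute, but this covariate nearly follows the genotype and does not separate them; an effect of the genotype stays open too.

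With 3 against 3 libraries there are 10 divisions of the libraries, too few for a share under 0.05. In edgeR the real one gave 2621 changed genes and 603 at 2-fold and the highest other 0 and 0, so 1 of 10 divisions reached each count. For the lists the real division gave 15 calls and the highest other 19, and 4 of 10 divisions, the real one included, gave at least 15. Every other division mixed the genotypes on both sides, so the difference between genotypes added to the spread within its groups. Few or no gene calls were therefore to be had there, and the 0 counts are no evidence against chance. Part of the difference between genotypes also remained between the sides. Neither the gene counts nor the list counts show how many would be called without a genotype difference.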
